A study of Mus musculus with 2 samples.

How the data were processed

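Histone H3 monomethylated at lysine 4 (H3K4me1), a mark known from enhancers and from the flanks of promoters, was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in mouse liver at embryonic day 13.5. The labels give strain B6NCrl, healthy embryos and pooled males and females. They name 2 libraries, biological replicates 1 and 2, called library 1 and library 2 here, which form 1 group. The labels also name a possible control experiment, which is not among the files used.

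Per the labels and the notes deposited with the samples, the 4 files analysed are peak lists in narrowPeak format on genome build mm10. Library 1's list was derived from its alignment and 2 further files, and library 2's list from its alignment and 1 further file. The pooled list was derived from both alignments and 2 further files, and the replicated list, per these notes, from the pooled list together with both libraries' own lists. The role of the further files, the aligner, the peak caller, its thresholds and the replication rule were not given in the sources used here. Each deposited peak has a whole-number score, an enrichment score per peak (called the enrichment value here; what it is relative to is not stated, and every value is above 1), a −log10 p-value, a −log10 q-value and the offset of its point source. Enrichment values and −log10 q-values were used as deposited, to rank, filter or describe peaks. Peak lists carry no read counts, so the depth of the libraries is unknown, and no interval below covers sequencing depth.

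Peaks on chromosomes 1 to 19 and X were analysed; no list has a peak on chromosome Y, and the few peaks on unplaced or unlocalised contigs were left out of the comparisons. Sequence came from GRCm38.p6 and genes from GENCODE M21. No peak ends beyond its chromosome. Coordinates are 1-based. Covered shares refer to the 2559.4 Mb of sequence without unknown bases.

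Overlap between the libraries was the share of peaks covered over at least 50% of their length by the other library's peaks, beside the same share in 100 circular shifts of the peaks along each chromosome. Intervals of counts are 95% Wilson intervals and cover counting only. Peak strengths were compared as log2 enrichment values across matched peaks. Genomic distribution was the share of covered bases in promoters (within 1 kb of a transcription start site, TSS, of any annotated gene), then exons, introns and intergenic sequence, over the same share in 100 circular shifts. TSS profiles give the share of protein-coding genes whose bin centre lies under a peak, in 100 bp bins to 5 kb on each side. A promoter is called CpG-rich where the observed over expected CpG ratio of the 1 kb around the TSS is at least 0.6.

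For each of 21728 protein-coding genes, coverage was the percent of a window, the gene body with 10 kb on each side, under a peak. Before the data were examined, 18 gene lists were fixed: erythroid, blood stem and progenitor, megakaryocyte, macrophage and myeloid, lymphoid, hepatoblast transcription factor, fetal hepatocyte secreted protein, adult hepatocyte metabolism, cholangiocyte, endothelial, stellate and mesenchymal, neural, cardiac and skeletal muscle, epidermal and lung epithelial, pancreas and intestine, germ cell, housekeeping and olfactory receptor. No gene is in more than 1 of them. Of the fixed symbols, Ahsp and Loricrin had no match in the annotation. A list's median was placed among the medians of 10000 random lists of the same size, matched on window length in 20 bins. A list at or above percentile 97.5 is called high and at or below percentile 2.5 low. The same was done for the difference library 1 minus library 2. Ratios of the libraries' coverages have 0.01 points added to each coverage, and the log2 ratios compared between erythroid and housekeeping genes 1 point. These percentiles describe 2 libraries; genes are not replicates and no p-value is given.

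Motif matches of 19 consensus sequences fixed before the data were examined were counted within 250 bp of the midpoints of 79417 replicated peaks over 2.5 kb from any TSS. The background was 76300 equally long regions 5 kb upstream or downstream, over 2.5 kb from any TSS and outside every pooled peak. The ratio of densities has a 95% interval from 1000 bootstraps over chromosomes, and stands beside ratios of up to 50 letter permutations of the same consensus. For the composite of an E-box and GATA, several spacings were counted together, and only the middle one was permuted. The way of counting was changed after motif results had been seen: simulated sequences showed that near-palindromic consensuses had been counted more than once per site, so matches on either strand are now counted without overlap. Domains are replicated peaks merged where at most 3 kb apart.

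The genes named are, by a rule fixed before the data were examined, the 3 members of each list with the highest coverage and the member with the lowest (ties by symbol), 8 well known loci, the genes at the 10 longest domains, the 10 genes with the highest coverage among windows of at least 20 kb that share no base with a higher one, the 5 genes with the largest difference between libraries in each direction, and the genes at the 5 peaks with the highest enrichment value. For some lists only part of the genes that this rule selects are given. Members of the gene families chosen after seeing the data are named outside this rule.

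There were 33 alternatives fixed before the data were examined. They covered a stricter threshold (−log10 q of at least 2), other overlap rules, another chance model, other windows, promoter sizes, backgrounds, merging gaps and matchings, and leaving out each replicate, where the other library's own list is used. A further 16 were chosen after seeing the data: 1 gene per 100 kb, autosomal genes, and matching on length in 5 bins, gene density in 5 bins and promoter CpG class. This matching with length in 20 bins, and matching on length in 5 bins by itself, with density or with CpG class, were also used. Each of these 5 was repeated with 1464 olfactory and vomeronasal receptor genes left out, as were matching on length in 20 bins and on length in 10 bins with CpG class. The remaining ones were, for the difference between libraries, matching on mean covered share and the strongest peaks of each library up to the covered bases of library 2.

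The steps were tested on simulated data. The covered bases of 500 of 500 simulated windows were recovered, and 19 of 19 planted motifs were counted within 10% of the number planted. On circularly shifted peaks, 15 of 340 list medians (4.41%) were called. Of 100 random lists of 20 genes, 8 were called high or low with nothing added. With coverage added to each gene only high calls were counted: 8 with 2 points, 18 with 5 points, 48 with 10 points and 100 with 20 points. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, numba 0.67.0, matplotlib 3.10.9 and bedtools 2.31.1 were used.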

Results

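H3K4me1 peaks were mapped in mouse liver at embryonic day 13.5, an organ known as a site of blood formation at this stage. The data comprise 2 biological replicate libraries of 1 group, with no second condition, so the lists were described and the libraries compared with each other. Library 1 had 192185 peaks that covered 115.6 Mb, and library 2 had 165262 peaks that covered 98.1 Mb. The mean was 178724 peaks ± 19037 (SD, n = 2), and the median peak width was 340 bp in library 1 and 341 bp in library 2. The pooled list held 197630 peaks on 136.9 Mb. The replicated list held 125908 peaks on 118.9 Mb, or 4.65% of the genome, with a median width of 599 bp. It was deposited under that name and made by a rule that was not given: 67.4% of its peaks were covered over at least 50% of their length in each library's deposited list, and 81.6% where 50% of the library's peak also sufficed, so not every peak in it is replicated by these rules. Peak lists do not give read depth, which is unknown. Values with ± below are means of both libraries' own lists with their SD (n = 2).

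Wide and strong H3K4me1 regions were found in both libraries, and most of the disagreement between the libraries lay among narrow, weak peaks. Peaks of library 1 were covered over at least 50% of their length by library 2 in 53.3% of cases (95% Wilson interval 53.1 to 53.5), and peaks of library 2 by library 1 in 71.0% (70.8 to 71.2). Circular shifts gave 4.09% ± 0.19 and 4.82% ± 0.23 (SD over 100 shifts), so the observed shares were 13.0 and 14.7 times those of chance. In the quartile with the highest enrichment values, 93.5% of library 1 peaks and 98.1% of library 2 peaks were shared. In the lowest quartile the shares were 25.6% and 49.1%. Of peaks at least 2000 bp wide, 99.9% of library 1's and 100% of library 2's were shared. The libraries had 79.5 Mb in common, 68.8% of library 1's covered bases and 81.0% of library 2's. Across 94805 matched peaks, which are not independent replicates, log2 enrichment values had a Pearson correlation of 0.724 and a Spearman correlation of 0.667. With 1 bp of overlap the ratios to chance were 9.27 and 9.87, and with reciprocal overlap 33.1 and 33.0. The replicated list held 63.7% of pooled peaks (63.5 to 63.9), from 19.5% in the quartile with the lowest enrichment values to 99.9% in the highest, and the 71722 pooled peaks not kept had a median width of 224 bp. When a pooled peak was instead required to be covered over at least 50% of its length by each library, the share was 42.9%.

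The mark was enriched at promoters and depleted in intergenic sequence relative to shifted peaks, while most peaks lay away from TSSs. Promoters held 22.0% of replicated peak bases against 6.44% by chance, a log2 ratio of 1.77 (libraries 1.76 ± 0.04). Introns held 52.6% against 40.4%, a log2 ratio of 0.38 (0.38 ± 0.01), and exons 5.52% against 3.43%, a log2 ratio of 0.69 (0.69 ± 0.01). Intergenic sequence held 19.9% against 49.7%, a log2 ratio of -1.32 (-1.31 ± 0.01). The midpoints of 79417 replicated peaks (63.1%) lay more than 2.5 kb from any TSS, and 30.4% lay more than 10 kb away. With promoters taken as 2.5 kb, the log2 ratio was 1.5 for promoters (39.8% of bases against 14.1% by chance), 0.25 for exons and 0.16 for introns. Sequence farther than 2.5 kb from any TSS thus held a smaller share of peak bases than of shifted peak bases.

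Around TSSs the peaks formed a pair of shoulders with a gap at the start site itself, and the shape differed by promoter class. Of 10075 genes with CpG-rich promoters, 19.6% were under a replicated peak at the TSS, 64.6% at 1150 bp downstream and 55.3% at 650 bp upstream. The rise from the TSS to the downstream maximum was 43.6 points ± 0.66 in the libraries. Of 11680 genes with CpG-poor promoters, 19.4% were under a peak at the TSS, 20.7% at 450 bp downstream and 20.4% at 250 bp upstream, and the rise was 1.09 points ± 0.09. The difference in rise between the classes exceeded the spread between the libraries; no test beyond that was run.

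**Figure D1:**
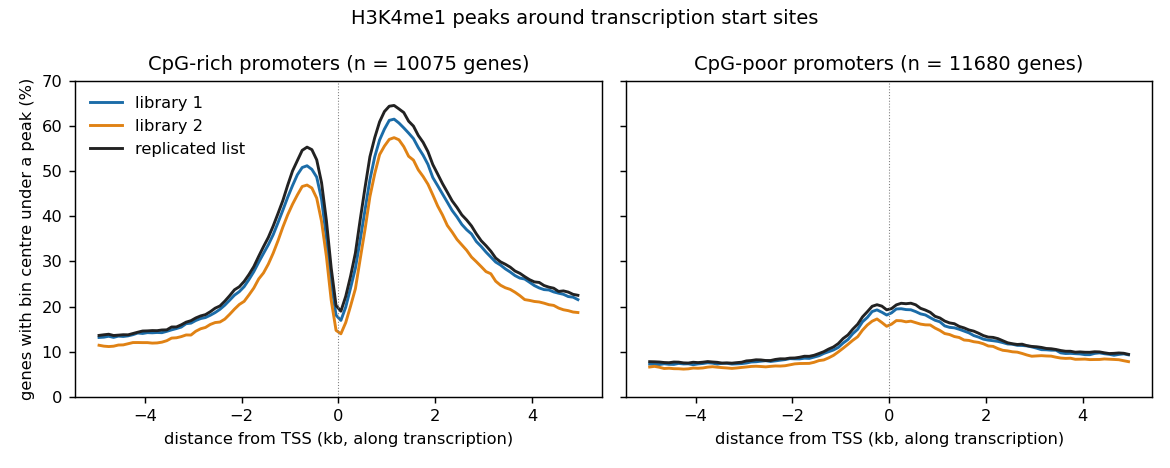
Share of genes (%) whose position lies under an H3K4me1 peak, by distance from the TSS in kb along transcription, for CpG-rich (left) and CpG-poor promoters (right). Lines show library 1, library 2 and the replicated list; CpG-rich promoters have 19.6% at the TSS and 64.6% at the downstream shoulder in the replicated list, and CpG-poor promoters 19.4% and 20.7%.

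Coverage differed between chromosomes, and chromosome X was the lowest in each list. Replicated peaks covered 0.717% of X and from 3.30% (chromosome 14) to 8.66% (chromosome 11) of the autosomes, with an autosomal median of 5.07%. Library 1 covered 0.667% of X and library 2 0.578%. In 1 Mb bins with at least 0.5 Mb of known sequence, X had 9.87 replicated peaks per Mb against 51.9 on the autosomes. It also had fewer TSSs, 28.7 per Mb against an autosomal median of 48.4, and a lower GC content, 39.2% against 42.0%.

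**Figure D2:**
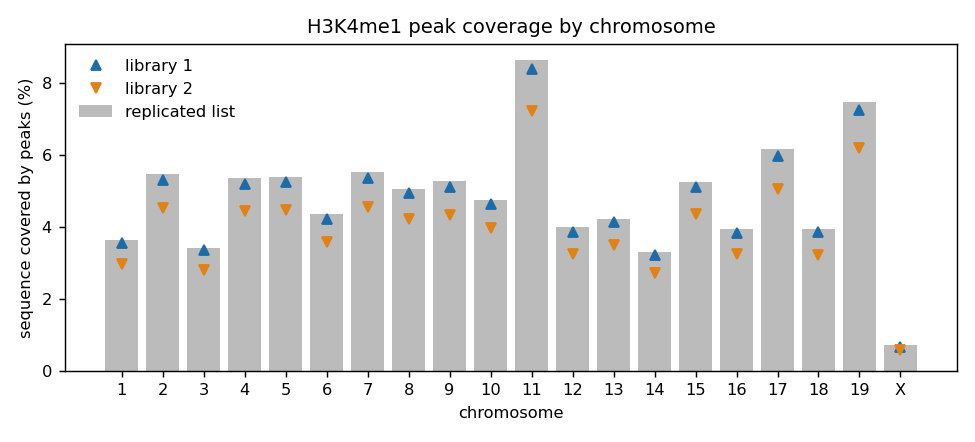
Percent of each chromosome's sequence covered by H3K4me1 peaks. Bars show the replicated list and triangles libraries 1 and 2; X stands at 0.717% in the replicated list, below the lowest autosome at 3.30%.

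Genes of red blood cells were the most covered of the lists compared, and those of adult hepatocytes were among the least. Of 18 lists, 4 were called high (erythroid, housekeeping, blood stem and progenitor, megakaryocyte), 2 low (olfactory receptor, adult hepatocyte metabolism) and 12 neither. The median gene had 7.35% of its window covered, and 5611 of 21728 genes (25.8%) had no replicated peak. For short genes most of the window is flank, such as for Cd68 (chromosome 11, 69664213 to 69666153) with a window of 21.9 kb. The coverage of a short gene's window may therefore lie at its neighbours.

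**Figure D3:**
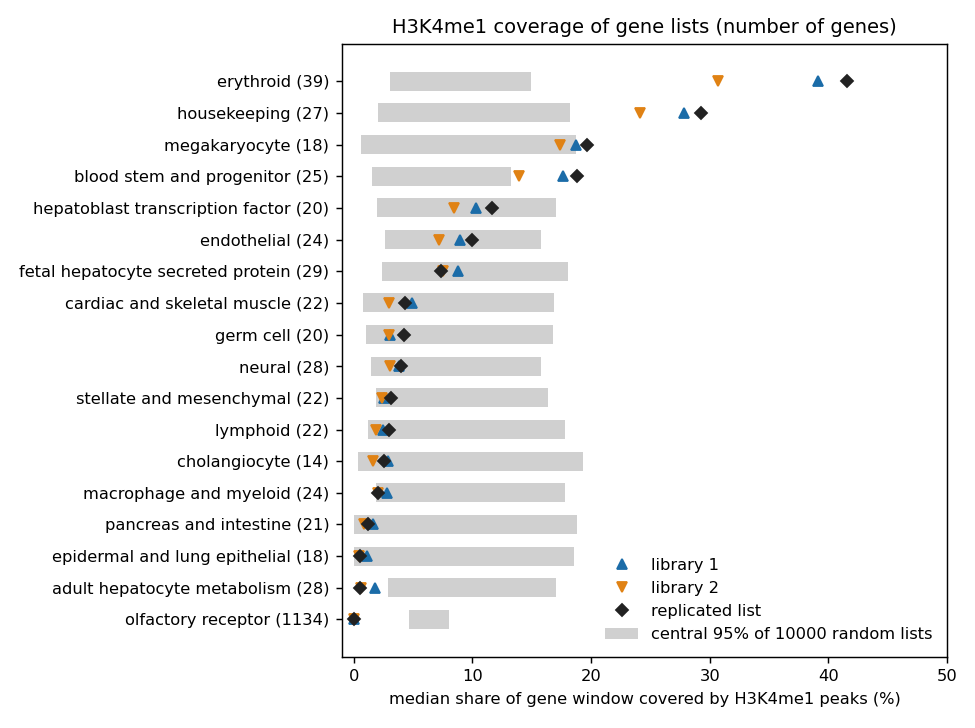
Median share (%) of gene windows covered by H3K4me1 peaks for the 18 gene lists, with the number of genes of each in parentheses. Diamonds show the replicated list, triangles libraries 1 and 2, and grey bars the central 95% of 10000 random lists matched on window length; the erythroid median of 41.6% stands farthest above its bar, which ends at 15%.

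The 39 erythroid genes had a median coverage of 41.6% (34.9% ± 6.0), above each of the 10000 random lists, whose median was 8.09%. Of these genes, 38 lay above the median of their length bin and 22 in its top 10%. Zfpm1, which encodes the GATA1 cofactor FOG1 (chromosome 8, 122282141 to 122337251), had 90.3% of its window covered (88.6% ± 2.0). Gfi1b, a transcriptional repressor needed for red cell and platelet formation (chromosome 2, 28609450 to 28621982), had 71.0% (68.1% ± 0.42), and Tal1, a basic helix-loop-helix factor of blood formation (chromosome 4, 115056426 to 115071755), had 67.9% (60.5% ± 1.6). The lowest member was Spta1, the alpha spectrin of red cells, with 4.88% (4.43% ± 0.57).

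The 25 blood stem and progenitor genes had a median of 18.8% (15.8% ± 2.6), at percentile 99.84; 20 lay above the median of their length bin and 10 in its top 10%. Lyl1, a relative of Tal1 (chromosome 8, 84701457 to 84704715), had 60%, the corepressor gene Cbfa2t3 52.1% and Lmo2, a partner of Tal1, 48.2%. Ptprc, which encodes CD45, was lowest with 0.528% (0.469% ± 0.48). The 18 megakaryocyte genes had a median of 19.6% (18.1% ± 0.93), at percentile 98.22, led by the platelet receptor genes Gp1ba with 56.2% and Itga2b with 42.4% and by Nbeal2 with 39.0%; 14 lay above the median of their length bin. Clec1b was among 2 members without a replicated peak. The megakaryocyte call ended in windows with 50 kb on each side (percentile 92.9) and with the mean in place of the median (percentile 97.0). It also ended with receptor genes left out of the lists matched on length (percentile 96.7, or 97.0 with 5 length bins).

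Other blood lists were not called. The 24 macrophage and myeloid genes had a median of 2.02% (2.42% ± 0.56), at percentile 2.83, with 10 members lacking a replicated peak, among them Adgre1, the macrophage marker F4/80. Its highest members were Cd68 (68.0%), the neutrophil elastase gene Elane (38.2%) and Ncf1 (35.8%). This list passed to low with gene bodies alone (percentile 0.785) and when also matched on gene density (percentile 1.27), and with receptor genes left out (percentile 0.91, 1.9 with 5 length bins and 0.52 with density added). With receptor genes left out and CpG class matched it stood at percentile 31.4, or 18.6 with density added. The 22 lymphoid genes had a median of 2.94% (2.19% ± 0.42), at percentile 8.91, with Cd79a, a B cell receptor component, at 45.7% and Cd3e, a T cell receptor component, at 0.

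Of the hepatocyte lists, 1 was called low and 2 were not called. The 28 adult hepatocyte metabolism genes had a median of 0.549% (1.20% ± 0.84), at percentile 0.11; 11 had no replicated peak and none lay in the top 10% of its length bin. Its median was 1.79% in library 1 and 0.605% in library 2. Its highest members were Glul, which encodes glutamine synthetase (27.7%), Hpd (24.4%) and Fah (23.2%), enzymes of tyrosine breakdown. Cps1, the first enzyme of the urea cycle, had 0. This call ended in windows with 50 kb on each side (percentile 2.97). In matchings chosen after seeing the data, with chemosensory receptor genes left out, it ended when matched on length in 5 bins, gene density and promoter CpG class (percentile 7.61), on the same with 20 length bins (4.6) and on length in 5 bins and CpG class (3.36), and held when matched on CpG class and length in 10 bins (1.97). With receptor genes in the pool these matchings bring so many random medians to 0 that this list could not be called low. The 20 hepatoblast transcription factor genes had a median of 11.7% (9.41% ± 1.3), at percentile 82.5, with Rxra, a nuclear receptor partner, at 59.8%, Creb3l3 at 42.6%, Foxa3 at 41.2% and Onecut1 lowest at 1.54%. The 29 fetal hepatocyte secreted protein genes had a median of 7.37% (8.16% ± 0.84), at percentile 30.1, with Serpinf2 at 40.6%, the apolipoprotein genes Apoa2 at 39.9% and Apoa1 at 35.8%, and albumin (Alb) at 0. Matched on length, density and CpG class, the hepatoblast list stood at percentile 97.0 and the fetal list at 95.9, or at 94.8 and 85.4 with receptor genes left out, so the fetal list moved to the other side of the random median.

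Among the remaining lists, the 27 housekeeping genes had a median of 29.3% (26.0% ± 2.7), at percentile 99.99, with the ribosomal protein gene Rpl13a at 75.2%, the glycolytic gene Gapdh at 63.5%, the tubulin gene Tubb5 at 60.5% and Emc7 lowest at 4.59%. Of 1134 olfactory receptor genes, 1085 had no replicated peak; their median was 0, below that of each random list. The highest were Olfr65 (chromosome 7, 103903487 to 103908650) at 30.2% and Olfr66 (103879443 to 103886252) at 26.7%, which lie near the beta globin gene Hbb-bs (103826534 to 103828096), and Olfr524 at 21.7%. Matching on CpG class could not test the olfactory receptor call, since the medians of random lists matched to it then reach 0 too often for it to be called low. The lists not called were endothelial (median 10%, libraries 8.07% ± 1.2; percentile 70.7, highest Egfl7 at 65.9%), cardiac and skeletal muscle (4.28%, 3.94% ± 1.3; percentile 25.3, Myl7 at 35.3%) and germ cell (4.23%, 3.02% ± 0.02; percentile 20.5, Gdf9 at 31.5%). So were neural (3.98%, 3.43% ± 0.54; percentile 16.9, Tubb3 at 37.5%), stellate and mesenchymal (3.11%, 2.43% ± 0.12; percentile 7.59, Cygb at 31.4%) and cholangiocyte (2.58%, 2.26% ± 0.93; percentile 14.1, Slc4a2 at 31.1%). The others were pancreas and intestine (1.21%, 1.27% ± 0.55; percentile 8.18, Cela1 at 46.8%) and epidermal and lung epithelial genes (0.556%, 0.801% ± 0.45; percentile 9, Foxj1 at 22.2%), for which a low call was not possible, as a list with no coverage would stand at percentile 3.08. The low medians depended on the library, with 1.12% in library 1 and 0.480% in library 2 for epidermal and lung epithelial, and 2.91% and 1.6% for cholangiocyte genes. Some of these were called low under other settings: with the mean in place of the median, the lymphoid, stellate and mesenchymal, epidermal and lung epithelial, pancreas and intestine and germ cell lists lay between percentiles 0.53 and 1.17, and with 50 kb windows the neural list lay at percentile 2.16. With receptor genes left out and matching on length, the epidermal and lung epithelial (1.99), lymphoid (2.42), pancreas and intestine (1.38) and stellate and mesenchymal lists (2.29) were low. With CpG class matched too and length in 10 bins, they stood at percentiles 17.4, 21.5, 3.82 and 7.79 and were not called. For the epidermal and lung epithelial list a low call was not possible there, as the lowest possible percentile was 5.67. This matching on CpG class and length without receptor genes made the neural list low (0.25) and took cardiac and skeletal muscle genes to percentile 62.6. With density added and length in 5 bins, the neural list was not called (percentile 7.49).

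The 8 loci fixed as well known ranged from 0 to 59.9% coverage. Gata1, the master regulator of red cell formation (chromosome X, 7959260 to 7978071), had 13 replicated peaks and 22.4% coverage (20.0% ± 0.41), and its strongest peak lay in its own intron (7969654 to 7971422; enrichment value 6.75). Hbb-bs had 10 peaks and 23.2% (22.7% ± 3.5), and the alpha globin gene Hba-a1 (chromosome 11, 32283511 to 32284465) 9 peaks and 59.9% (56.7% ± 5.5). Gata2, a regulator of blood stem cells (chromosome 6, 88193891 to 88207032), had 12 peaks and 44.2% (35.8% ± 0.62), and Runx1 (chromosome 16, 92601466 to 92826149) had 50 peaks and 34.8% (32.0% ± 2.7). Hnf4a, a regulator of hepatocyte identity (chromosome 2, 163506808 to 163572910), had 15 peaks and 16.7% (14.8% ± 1.0). Afp, the fetal plasma protein gene (chromosome 5, 90490737 to 90508907), had 1 replicated peak and 1.5% (1.67% ± 0.24). Alb (chromosome 5, 90460897 to 90476602) had none, although library 1 had 2 peaks in its window, library 2 had 1 and the pooled list had 2 (libraries 1.03% ± 0.01).

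Library 1 covered more of most genes than library 2. Its coverage was higher at 14547 of 21728 genes (67.0%), with a median difference of 0.887 points over all genes, and across genes, which are not independent replicates, the libraries' coverages had a Pearson correlation of 0.992 and a Spearman correlation of 0.988. The difference, library 1 minus library 2, was high for the erythroid (3.45 points, percentile 100, higher at 34 of 39 genes), housekeeping (3.09 points, percentile 99.8, 26 of 27) and blood stem and progenitor lists (2.76 points, percentile 99.94, 19 of 25), low for olfactory receptors (0 points, percentile 0.355) and not called for the other 14. Of 1134 olfactory receptor genes, 53 were higher in library 1 and 17 in library 2, and 1085 had no replicated peak. Their median of 0 follows from this lack of coverage, so that low call says nothing about a difference between the libraries. With the stricter q the hepatoblast transcription factor list was high (percentile 99.6). This order holds in percentage points only: the median ratio of library 1 to library 2, with 0.01 points added to each, was 1.12 for erythroid, 1.11 for housekeeping and 1.13 for blood stem and progenitor genes, below 1.21 for cardiac and skeletal muscle and 1.20 for neural genes. The largest single differences were at G430095P16Rik, with 83.7% in library 1 and 68.9% in library 2, Castor1 (57.0% and 42.2%), Plekhj1 (47.8% and 33.2%), Mpg (62.9% and 48.7%) and Ltb (39.3% and 25.1%). In the other direction they were Rps16 (31.7% and 39.0%), Inppl1 (4.34% and 11.4%), Pdlim2 (15% and 20.6%), Slc25a34 (8.11% and 13.7%) and Slc35b2 (50.6% and 55.6%). Each value is from 1 library and has no replicate check. With random lists matched on the mean coverage of both libraries, the high calls ended (erythroid at percentile 46.1, housekeeping at 70.4, blood stem and progenitor at 89.7). With equal numbers of the strongest peaks, erythroid (2.36 points, percentile 100) and blood stem and progenitor genes (1.42 points, percentile 99.1) stayed high, while housekeeping (1.13 points, percentile 91.0) and olfactory receptors (percentile 49.6, where random lists were at 0 as well) were not called; library 1 still covered 108.4 Mb against 98.1 Mb. With the strongest peaks up to equal covered bases, chosen after seeing the data, 129358 peaks of library 1 stood against 165262 of library 2. Erythroid genes stayed high there (0.602 points, percentile 99.8), blood stem and progenitor (-0.583 points, percentile 0.05) and housekeeping genes (-0.239 points, percentile 1.46) became low, and so did hepatoblast transcription factor (percentile 0), fetal hepatocyte secreted protein (percentile 0.01), endothelial (percentile 1.91) and lymphoid genes (percentile 2.39).

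Most binding motifs of blood and liver transcription factors were denser in distal peaks than in their flanks, and so were several motifs of other factors. The GATA motif was 2.14 times as dense (95% interval over chromosomes 2.07 to 2.20; libraries 1.97 ± 0.08), with 0 of 50 permuted consensuses as high. The composite of an E-box and GATA, known as a site of the TAL1 and GATA1 complex, was 2.78 times as dense (2.58 to 3.01; 2.37 ± 0.26), also with 0 of 50. These permutations scramble its GATA part as well, so they do not test what the E-box part adds to GATA. KLF, the family of the erythroid factor KLF1, had a ratio of 1.85 (1.80 to 1.90), AP1/NFE2 1.31 (1.26 to 1.36), RUNX 1.13 (1.09 to 1.18), ETS 1.73 (1.61 to 1.86) and PU.1 1.51 (1.45 to 1.58). For ETS and PU.1, 1 of 50 permuted consensuses was as high, and for KLF, AP1/NFE2 and RUNX 0 of 50. Among factors of hepatocytes, CEBP had a ratio of 2.35 (1.74 to 3.20, from 115 matches), HNF4A 1.58 (1.44 to 1.75) and FOXA 1.14 (1.09 to 1.19), each with 0 of 50. Against a background matched on GC content, HNF4A had a ratio of 1.45 (1.21 to 1.74) with 5 of 50 permuted consensuses as high, ETS and PU.1 had 2 of 50 each, and CEBP, FOXA, KLF, AP1/NFE2 and RUNX 0 of 50. HNF1 had 1.03 (0.686 to 1.63, from 30 matches), which spans 1, and 2.12 against the matched background, with 2 of 50 as high and an interval from 0.842 with no upper bound.

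Of the other motifs, TEAD had a ratio of 1.20 (1.17 to 1.24) and MEF2 1.11 (1.00 to 1.24), each with 0 of 50 permuted consensuses as high. MEF2 was at 1.03 in library 1's own list. RFX had 2.43 (1.41 to 5.24, from 43 matches), with 2 of 11 as high. MYOD had 1.40 (1.33 to 1.48), with 4 of 50 as high, and CTCF 1.79 (1.55 to 2.11), with 13 of 50 as high. P63 spanned 1, at 1.09 (0.911 to 1.25). NEUROD, at 0.881 (0.851 to 0.915), and POU, at 0.734 (0.691 to 0.777), were less dense than in the flanks, with 49 and 41 of 50 permuted consensuses as high. Distal peaks had a GC content of 47.4% and the flanks 44.0%. Against flanks matched on GC content, GATA had a ratio of 2.59, TEAD had 1 of 50 permuted consensuses as high, MYOD 6 of 50 and CTCF 7 of 45, POU was at 0.965 (0.887 to 1.05), and RFX at 2.03 with an interval from 0.803 and no upper bound. NEUROD was at 0.883 (0.842 to 0.939) there, with 10 of 50 permuted consensuses as low, and for POU 14 of 50 were as low.

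**Figure D4:**
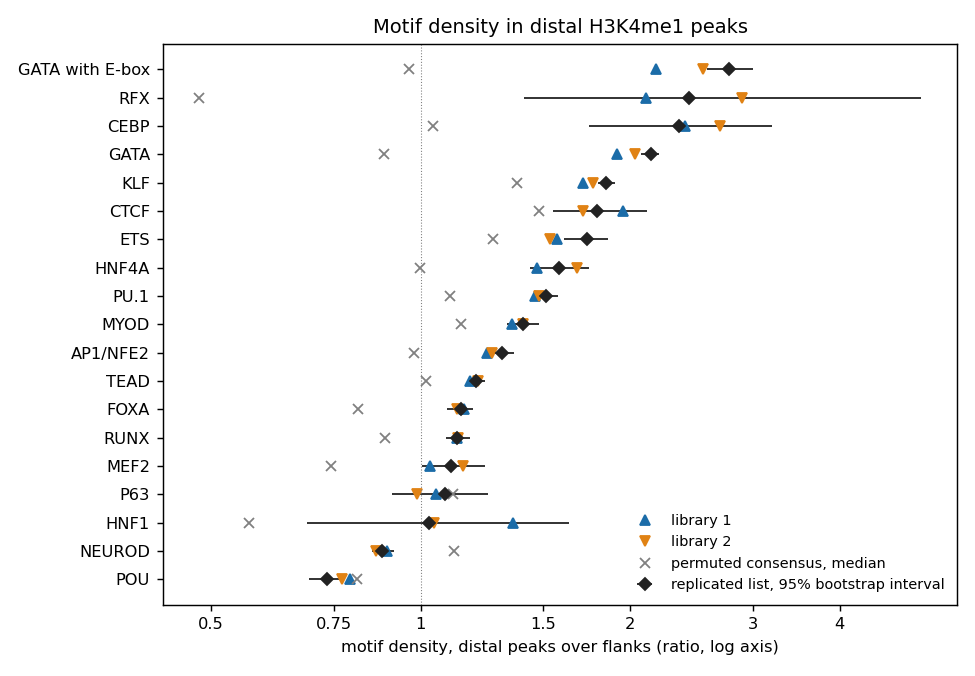
Ratio of motif density in distal H3K4me1 peaks to that in flanking regions, on a log axis, for 19 motifs. Diamonds with lines show the replicated list with its 95% bootstrap interval over chromosomes, triangles libraries 1 and 2, and crosses the median of permuted consensuses; GATA with E-box is highest at 2.78 and POU lowest at 0.734.

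Merging replicated peaks at most 3 kb apart gave 43659 domains, of which 4292 were at least 10 kb long. The longest, 179 kb on chromosome 6 (38754575 to 38933652), overlapped the kinase gene Hipk2 and Tbxas1, and had 78.8% of its length under replicated peaks (71.3% ± 3.7). The maximum length depended on the list and on the gap. The longest domain at any locus was 129 kb in library 1's own list and 127 kb in library 2's. It was 91.3 kb in the replicated list with a gap of 1 kb. The next were at Cmip (127 kb), Ssbp3 (116 kb), Mbnl1 (115 kb), Mtss1 (112 kb), 7 genes including Sbno2, Stk11 and Midn (106 kb), Gse1 (104 kb and 100 kb), Zmiz1 (100 kb) and Slc22a23 (95.6 kb). With a merging gap of 1 kb, 1733 domains were at least 10 kb long, and 4 of the 10 named above were among the 10 longest, against 7 in library 1's own list and 9 in library 2's.

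The single widest peak, 48438 bp on chromosome 8 (122284106 to 122332543), overlapped Zfpm1 and the annotated gene Gm20388 and had an enrichment value of 17.0. The highest enrichment values were 17.8 for a peak at Mfsd12 and Fzr1 (chromosome 10, 81358066 to 81368424), 17.7 for a peak 38321 bp from Ggta1 (chromosome 2, 35501553 to 35506120), 17.6 at Mafk, a partner of NFE2 (chromosome 5, 139801071 to 139807308), and 17.2 at Cic (chromosome 7, 25279007 to 25281910), followed by the Zfpm1 peak. By coverage of the gene window, the top genes were Pnpo, the last enzyme of vitamin B6 activation (92.4%; libraries 90.7% ± 1.3), Btg2, an antiproliferative gene (92.0%; 87.9% ± 3.1), Junb, an AP1 subunit (91.8%; 87.4% ± 0.69), and Zfpm1 (90.3%). They were followed by E030018B13Rik (88.8%), Midn (87.5%), Gpr146 (86.9%), Naprt (86.6%), Lmntd2 (86.3%) and Ypel4 (85.8%).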

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

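Signal outside the chromosomes analysed drew attention to a few peaks that no comparison used. Library 1 had 4 peaks on unplaced or unlocalised contigs, library 2 had 4 and the pooled list 5, each above 3, a fixed cutoff for flagging. The replicated list had 2. On contig JH584304, peaks starting at 58870 and 59512 were in the pooled and the replicated list, with enrichment values of 1.6 and 1.69 and −log10 q-values of 11.3 and 17.1. Both libraries had overlapping peaks there: library 1's had enrichment values of 1.62 and 1.72, and library 2's 1.73 and 1.88. No list had a peak on chromosome Y or on mitochondrial DNA. No explanation of these peaks was tested.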

How the results depend on the processing

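Of 588 alternative values for 82 results, 34 moved, 22 weakened, 27 passed the threshold and 4 reversed. The others stayed within the limit set for their kind of result. This was the spread between libraries for genomic distribution, TSS profiles and peak widths, and the counting interval for overlaps and the replicated share. It was an interval over peaks for correlations, a fixed factor for peak numbers and domains, and the side of the threshold for gene lists and motifs. The matchings that leave out receptor genes, those on CpG class, on length in 5 bins and on mean coverage, the equal covered bases, and the sets of autosomal genes and of 1 gene per 100 kb, were chosen after seeing the data. Merging overlapping peaks moved nothing, since no list has any. Read depth is unknown, so its effect could not be tested. Unless stated, the cause was not tested.

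Peaks of library 1 and library 2 shared by the other library were 52.3% and 75.3% with a −log10 q of at least 2 (13.9 and 16.5 times chance), 63.9% and 79.3% with an overlap of at least 1 bp (9.27 and 9.87 times) and 40.9% and 47.6% with reciprocal overlap (33.1 and 33.0 times); the last 2 rules loosen or tighten the overlap by construction. Shuffled peaks gave 14.6 times for library 2. With the stricter q the Spearman correlation of strength was 0.661 and the replicated share 68.7%; requiring coverage by each library gave 42.9%.

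Promoters within 2.5 kb gave log2 ratios of 1.5 (promoter), 0.25 (exon), 0.16 (intron) and -1.5 (intergenic), and TSSs of coding genes 2.18 (promoter), 0.39 (intron) and -1.29 (intergenic). Without each replicate in turn, the promoter ratio ranged from 1.73 to 1.78 and the intergenic from -1.32 to -1.30. Likewise, coverage at the TSS ranged from 15.2% to 18.0% (all genes), 14.3% to 17.5% (CpG-rich) and 15.9% to 18.4% (CpG-poor), and the downstream maximum from 34.3% to 37.3%, 57.4% to 61.5% and 16.9% to 19.5%. Single lists hold fewer covered bases than the replicated list.

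Leaving out either replicate changed no call of the gene list medians. The adult hepatocyte list lost its low call with 50 kb windows (percentile 2.97) and when matched on length in 5 bins, density and CpG class (percentile 32.4; percentile 7.61 without receptor genes), on the same with 20 length bins (20.9; 4.6) and on length in 5 bins and CpG class (18.3; 3.36). These 3 matchings in the full gene set are void for this list and for olfactory receptors (percentiles 17.5, 43.7 and 49.9): a list with no coverage would not have been called low. The megakaryocyte list lost its high call with 50 kb windows (percentile 92.9), with means (percentile 97.0) and when matched on length without receptor genes (percentile 96.7, or 97.0 with 5 bins). Lists that became low were, with means, epidermal and lung epithelial (percentile 0.53), germ cell (percentile 0.92), lymphoid (percentile 1.1), pancreas and intestine (percentile 0.91) and stellate and mesenchymal (percentile 1.17). With gene bodies they were germ cell (percentile 1.28) and macrophage and myeloid (percentile 0.785), with density matching macrophage and myeloid (percentile 1.27), and with 50 kb windows neural (percentile 2.16). When matched on length without receptor genes they were epidermal and lung epithelial (percentile 1.99), lymphoid (percentile 2.42), macrophage and myeloid (percentile 0.91), pancreas and intestine (percentile 1.38) and stellate and mesenchymal (percentile 2.29), and, with CpG class added, neural (percentile 0.25). With length in 5 bins and no receptor genes they were macrophage and myeloid (percentile 1.9), pancreas and intestine (percentile 1.77) and stellate and mesenchymal (percentile 2.31). With density added to that they were epidermal and lung epithelial (percentile 1.66), lymphoid (percentile 1.16) and macrophage and myeloid (percentile 0.52), and with CpG class added neural (percentile 0.32, or 0.75 in the full gene set).

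For the difference between libraries, matching on mean coverage took the erythroid list to the other side of the median (percentile 46.1) and ended the calls of blood stem and progenitor (percentile 89.7) and housekeeping genes (percentile 70.4). Equal peak numbers kept those of erythroid (percentile 100) and blood stem and progenitor genes (percentile 99.1) and ended those of housekeeping genes (percentile 91.0) and olfactory receptors (percentile 49.6, void with random lists at 0), and the stricter q made hepatoblast transcription factors high (percentile 99.6). Equal covered bases kept erythroid genes high (percentile 99.8), left olfactory receptors at percentile 50, again void, and reversed blood stem and progenitor (percentile 0.05), housekeeping (percentile 1.46) and hepatoblast transcription factor genes (percentile 0). They made endothelial (percentile 1.91), fetal hepatocyte secreted protein (percentile 0.01) and lymphoid genes (percentile 2.39) low. MEF2 ranged from 1.03 to 1.15 without each replicate, and a background matched on GC content took POU to 0.965, with an interval spanning 1, and RFX to 2.03, with one reaching below 1. A merging gap of 1 kb gave 1733 domains of at least 10 kb, 4 of the 10 longest being shared and the longest 91.3 kb; a smaller gap merges fewer peaks by construction.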

Other observations

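The gene families in this and the next paragraph were chosen after seeing the data, as 20 patterns of gene symbols compared with random lists matched on window length. Replication-dependent histone genes had the highest median coverage, 45.7% (libraries 39.8% ± 3.9, SD, n = 2; percentile 100, 67 genes), led by Hist1h4b with 65.5%; these genes are clustered and share peaks. Immediate early genes had 31.8% (29.2% ± 0.03; percentile 99.8), with Junb at 91.8% and Ier3 at 72.6%. Ribosomal protein genes had 30.4% (27.7% ± 1.9; percentile 100), glycolysis genes 30.5% (27.2% ± 2.2; percentile 99.9) and autophagy genes named Atg 18.0% (15.2% ± 2.6; percentile 99.4). The red cell membrane skeleton had 33.7% (30.5% ± 3.5; percentile 100), led by Tpm1 with 53.4%, and heme synthesis 34.2% (30.8% ± 2.1; percentile 99.7), led by Alad with 64.7%. Of these families, heme synthesis shares 7 of 8 genes with the lists fixed earlier, the membrane skeleton 5 of 13, glycolysis 3 of 13 and ribosomal proteins 3 of 83. Without shared genes the skeleton, glycolysis and ribosomal families were at percentiles 100, 99.9 and 100.

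Families with low coverage were vomeronasal receptors, cytochrome P450 genes and clustered protocadherins, each with a median of 0 at percentile 0, keratins (0, percentile 0.98), collagens (0.854%, libraries 1.08% ± 0.34; percentile 0.01), zinc finger genes named Zfp (6.66%, percentile 0.1) and potassium channels (3.0%, percentile 1.78). Of 100 cytochrome P450 genes, 62 had no covered base, while Cyp2w1 had 52.9%. Unlike the fixed lists, the families were not also tested with spaced genes only. Neighbouring members, such as clustered protocadherins, therefore counted as separate genes. The percentiles of clustered families, high or low, thus rest on fewer separate loci than genes and are less firm than they look. Proteasome subunits (13.6%, percentile 89.6), Hox genes (4.82%, libraries 4.06% ± 1.5; percentile 18.5), minichromosome maintenance genes (19.0%, percentile 83.7), Slc transporters (9.48%, percentile 92.9) and interleukins (3.39%, 3.42% ± 1.3; percentile 6.3) were not called, and defensins (0) could not have been called low.

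In the patterns that follow, the tests of more peaks, of gain in proportion to coverage and of more erythroid cells in library 1, and that of promoter class with gene density, were chosen after values related to their results had been seen. Each pattern itself was found in these data, and with 1 group no biological explanation from the design was tested.

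Chromosome X had far lower coverage than the autosomes (0.717% against a median of 5.07%). A model of GC content and TSS number in 1 Mb bins of the autosomes left X at 0.448 of its predicted coverage. This was below the autosomes' 0.760 to 1.25 (SD 0.121), so these features as modelled do not account for it alone. X had fewer TSSs (28.7 per Mb) than the lowest autosome (38.6) and a lower GC content (39.2% against 40.5%). The activity of genes was not modelled, so gene content is not excluded. A lower dose of the mark on X, as fewer copies in male embryos or an inactive copy in female embryos could give, predicts that strong peaks are lost more than all peaks. Strong peaks had an enrichment value of at least 6.04, the 90th percentile of autosomal peaks. Their X over autosome density was 0.167 (bootstrap interval 0.0975 to 0.245) of that of all peaks. There were 27 strong peaks among the 1613 on X in 1 Mb bins with at least 0.5 Mb of known sequence. A lower dose predicts this, but so does any other cause of weaker signal on X, so the ratio does not single out dose. That ratio was not adjusted for gene content, and how the peak caller or the mapping of reads treats X was not tested.

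Erythroid, blood stem and progenitor and housekeeping genes gained most coverage in library 1 over library 2 in percentage points, though not as median ratios (1.12, 1.13 and 1.11 with 0.01 points added, against 1.21 for cardiac and skeletal muscle genes). With equal numbers of the strongest peaks, the first 2 gains stayed at percentiles 100 and 99.09, and that of housekeeping genes stood at percentile 90.98. That setting also removes weak peaks of library 1 alone, and library 1 still covered 108.4 Mb against 98.1 Mb. It therefore cannot tell whether more peaks in library 1 account for these gains. Gain in proportion to coverage is a candidate explanation for each: among lists matched on mean coverage they stood at percentiles 46.11, 89.71 and 70.44. With equal covered bases erythroid genes stayed high (percentile 99.79) and the others became low (percentiles 0.05 and 1.46), in a setting that removes weak peaks of library 1 alone by construction. More erythroid cells in library 1 would raise erythroid above housekeeping genes, and their difference in median log2 ratio of 0.00799 with 1 point added to each coverage (95% of permutations from -0.062 to 0.071) decides nothing, so cell content stays open.

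Erythroid genes were the most covered list and adult hepatocyte genes among the least. Promoter CpG class and gene density do not account for the erythroid list, which stayed at percentile 100 among lists matched on both and on length. Whether they account for the adult hepatocyte list cannot be told: with receptor genes left out it moved to percentile 7.61, against a lowest possible 1.83, while CpG class without density left it at percentile 3.36 with 5 length bins and 1.97 with 10, on either side of the threshold. With receptor genes in the pool, matching on both was void, since a list with no coverage would have stood at percentile 8.86. Which cell types carried the mark cannot be read from tissue, and the share of erythroid cells was not measured.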
